A study of Mus musculus with 16 samples.

How the data were processed

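Total RNA from subcutaneous white adipose tissue of C57BL/6J mice was sequenced after ribosomal RNA removal with a Ribo-Zero Gold kit, per the labels' protocols. The mice were adipocyte-specific Nampt knockouts (ANKO, made with an adiponectin-Cre transgene and floxed Nampt) and flox/flox controls on regular chow. Young mice were 2 months old and old mice 22 to 27 months, per the labels, and the series title names female mice. The 16 libraries, 1 per sample, fell into 4 groups: 3 young control, 3 young ANKO, 5 old control and 5 old ANKO. Whether each library came from a separate animal is not given in the sources used here, so p-values measure the spread between samples only. The labels place all libraries on the same flow cell and lane and give no batch. The exons of Nampt that were floxed are not given in the sources used here.

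The deposited table held raw read counts per gene symbol, with 1 column per library and no normalization. The submitters' processing notes name STAR (2.0.4b), Subread and featureCounts (1.45) and the genome build GRCm38. They give no annotation release, filter or strand setting, so counts of genes that overlap another gene's exons, on either strand, are uncertain. The same holds for members of gene families with near-identical sequence, since the handling of reads with several matches is not given. Of 40757 lines, 322 repeated another line in full and 113 were dropped because a line of the same symbol held more reads, which left 40322 symbols. A further 24 symbols had been turned into dates by a spreadsheet. They held 0.126% of all reads and were kept under those names.

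Library totals were 22586600, 19747700 and 20302600 reads in young controls and 23858600, 23732500 and 20417600 in young ANKO libraries. They were 23547300, 30779300, 19418400, 19277400 and 29519900 in old controls and 19367900, 20060200, 21755500, 20963500 and 20773800 in old ANKO libraries. Positions were taken from the GENCODE M21 annotation of GRCm38 by gene symbol.

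Values in CPM (counts scaled to effective library size) were computed with edgeR (4.0.16, in R 4.3.3) from the deposited counts with TMM factors, after the filter filterByExpr by group, which kept 21206 genes. Changed genes were called with edgeR's quasi-likelihood F-test (robust dispersions and robust fit) from 1 model of the 4 groups over all 16 libraries. The adjustment was Benjamini-Hochberg over all genes of a comparison with a threshold of 0.05. Each fold change is given on the log2 scale with its standard error, taken as its size over the square root of F. The comparisons were ANKO against control in young and in old mice, old against young in control and in ANKO mice, and the difference between the ANKO effects at both ages. All adjusted p-values below come from this edgeR test unless another tool is named.

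Before the data were examined, 41 gene lists were fixed. They covered NAD metabolism, adipocyte function, mitochondria, stress, inflammation, clock and ageing genes, markers of cell types that the depot can hold, the genes next to Adipoq and a small set for a check of sex. Of their 830 genes, 21 stood in 2 or more lists. The 40 lists with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the lists. The number of members past the threshold is given over all genes and, separately, adjusted over the list alone. The list tests were repeated with the correlation estimated for each list and with fry, a rotation test of whether a list's genes move one way on balance.

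The genes named were set by a rule, also fixed before the data were examined. For each comparison it took Nampt and the 6 highest and 6 lowest fold changes among genes past the threshold whose groups of libraries did not overlap in CPM. Their mean had to be at least 1 CPM over the 16 libraries, and predicted gene models and immunoglobulin and T-cell receptor segments were left out. It added up to 4 members with the smallest p of each list described, and members set side by side in different comparisons. For the difference between ages it took the 6 smallest p-values in each direction, without the condition on overlap. Any gene outside this rule is named as such.

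The pipeline was tested on simulated counts with the real means and library sizes, in which genes were changed by 2-fold or 4-fold. For young ANKO against control, run on 20889 genes, it recovered 26.3% of 2-fold and 62.2% of 4-fold changes. For old ANKO against control (20883 genes) it recovered 39.8% and 65.0%. For old against young it recovered 31.3% and 73.7% in controls (20913 genes), and 37.4% and 71.4% in ANKO libraries (20897 genes). For the difference between ages (20866 genes) it recovered 7.07% of 2-fold and 48.0% of 4-fold changes. The simulations gave between 2 and 4 false calls each.

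The alternatives tried were RLE size factors and library totals in place of TMM, no filter and a stricter filter (1 CPM in 3 libraries), a fit of only the libraries compared, and DESeq2 (1.42.0) and limma-voom in place of edgeR. Others left out mitochondrial, haemoglobin, immunoglobulin and milk genes, used the replicate number as a block, or left out each library in turn. Chosen after seeing the data were a skeletal muscle score as a covariate, the removal of old control libraries 2 and 5 together, the removal of old control library 2, and the removal of abundant non-coding RNA.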

Results

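Gene expression was measured by RNA sequencing of subcutaneous white adipose tissue from 16 samples: 3 young control, 3 young ANKO, 5 old control and 5 old ANKO. The design asked how deletion of Nampt, the gene of the enzyme that makes NAD from nicotinamide, in adipocytes changes the transcriptome of this fat depot at 2 months and at 22 to 27 months of age. Totals ranged from 19277400 to 30779300 reads per library, and 21206 genes were tested. Xist, which is transcribed from the inactive X chromosome, lay between 1567 and 2124 CPM in the 16 libraries. Xist and Tsix were the 2 genes of the 6 in the sex check list that passed the filter on low counts, and their median log2 fold change between ANKO and control was -0.10 at both ages.

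Nampt (chromosome 12, 32819545 to 32853349) was lower in ANKO fat of young mice. Its level was 86.3, 95.4 and 89.0 CPM in the young controls and 49.8, 51.7 and 48.7 CPM in the young ANKO libraries. The log2 fold change was -0.85 ± 0.17 (SE, n = 3 per group; edgeR adjusted p = 0.0429; 7.58e-04 to 0.257 over the alternatives tried). The call was lost when any 1 of the 6 young libraries was left out, while the log2 fold change stayed between -0.87 and -0.80. The adjusted p was then 0.0927, 0.194 and 0.257 without young control 1, 2 and 3, and 0.136, 0.189 and 0.184 without young ANKO 1, 2 and 3. In old mice Nampt was 61.2, 76.9, 47.2, 50.7 and 78.6 CPM in controls and 47.6, 48.2, 52.0, 45.0 and 54.1 CPM in ANKO libraries. The old difference did not pass the threshold (log2 fold change -0.35 ± 0.13, n = 5 per group, edgeR adjusted p = 0.0945), and old controls 3 and 4 lay within the range of the old ANKO libraries. It passed without old control 3 (-0.44, edgeR adjusted p = 0.0188) or without old control 4 (-0.42, adjusted p = 0.0443). Without old controls 2 and 5 it was -0.08 (edgeR adjusted p = 0.738). Over the alternatives tried the adjusted p ran from 0.0188 to 0.738. Reads over the whole gene and from all cell types of the tissue enter these values. Adipoq, the adipocyte hormone adiponectin, was 405.5 to 1473 CPM in old controls and 62.0 to 136 CPM in old ANKO libraries, so the 2 labelled groups were separate for this gene.

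**Figure D1:**
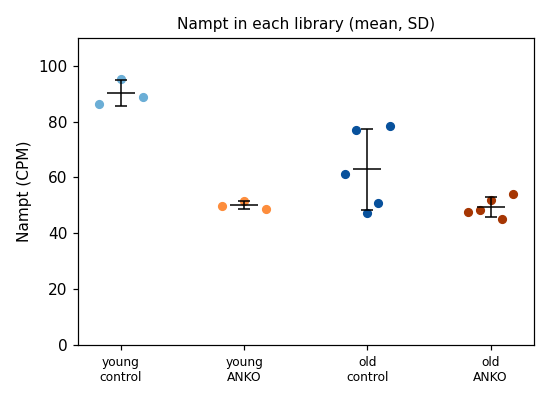
Level of Nampt in CPM in each of the 16 libraries (points), with the group mean and SD (black bars). The young ANKO libraries sit between 48.7 and 51.7 CPM, below the young controls at 86.3 to 95.4 CPM, and the old groups overlap.

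In young mice genes of the stress response were higher and adipocyte genes lower in ANKO than in control fat. Gdf15, a secreted factor of the cellular stress response (chromosome 8, 70629393 to 70632456), rose from 0.777 ± 0.760 to 28.2 ± 9.28 CPM (SD, n = 3 per group; log2 fold change 5.19 ± 0.78 SE, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0114). Maoa, which degrades monoamines, rose by 2.75 ± 0.34 (edgeR adjusted p = 0.00312). Tsku, a secreted proteoglycan made by liver and fat, rose by 2.74 ± 0.26 (adjusted p = 2.87e-04), and Cbr3, a carbonyl reductase, by 2.37 ± 0.31 (adjusted p = 0.00376). Gpnmb, a lysosomal glycoprotein of lipid-loaded macrophages, rose by 3.27 ± 0.64 (adjusted p = 0.0442) and Lctl, a glycosidase-like membrane protein whose exons overlap those of Zwilch, by 2.98 ± 0.57 (adjusted p = 0.0429). The lowest values were those of Hcar1, the lactate receptor of adipocytes (-2.88 ± 0.42, edgeR adjusted p = 0.0112), Pck1, which supplies glycerol for fat storage (-2.73 ± 0.47, adjusted p = 0.0236), and Rbp4, the retinol carrier (-2.62 ± 0.39, adjusted p = 0.0113). Cxcl11, a chemokine gene annotated as a polymorphic pseudogene, with exons that overlap another gene (-2.41 ± 0.44, adjusted p = 0.0310), the hormone gene Retn (-2.26 ± 0.35, adjusted p = 0.0132) and the matrix gene Spon1 (-2.19 ± 0.30, adjusted p = 0.00669) fell as well. In all of these genes the groups did not overlap, as the naming rule required. Maoa, Tsku and Cbr3 kept their call without each young library in turn. The other 9 lost it without young ANKO 2 and at least 1 further library, with a highest adjusted p from 0.0592 (Spon1) to 0.241 (Gpnmb).

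Of 21206 genes, 67 passed in young mice, 35 higher and 32 lower, 57 by at least 2-fold. More passed in a fit of the young libraries alone, with only their spread. At an unadjusted p under 0.05 there were 1527 genes. All 67 had groups that did not overlap, which is no separate evidence. The count was 33, 18 and 10 without young control 1, 2 and 3, and 48, 10 and 14 without young ANKO 1, 2 and 3. Passing without each library in turn were 8 genes, among them Maoa, Tsku, Cbr3, Ephx1, an epoxide hydrolase (1.52 ± 0.15, edgeR adjusted p = 2.87e-04), and Acot11, a thioesterase of the thermogenic list (2.35 ± 0.26, adjusted p = 0.00107). The other 3, chosen after their values were seen, were the transporter Abcc4 (0.95 ± 0.11, adjusted p = 0.00208), the zinc finger gene Zfp949 (1.44 ± 0.13, adjusted p = 2.49e-04) and the uncharacterised 9630013D21Rik (-1.98 ± 0.25, adjusted p = 0.00330). The exons of Ephx1 and Acot11 overlap other genes. Of the 26 called genes that the naming rule covers, 22 lost the call without young ANKO 2, and most of these without several other libraries too (highest adjusted p = 0.257).

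Genes of the integrated and mitochondrial stress response were higher in young ANKO fat, with 4 of 24 over all genes and 10 adjusted over the list alone (median log2 fold change 0.42, limma camera adjusted p = 4.94e-08; adjusted p = 0.193 with an estimated correlation). Besides Gdf15 these were the transcription factors Atf3 (2.21 ± 0.37, edgeR adjusted p = 0.0208) and Atf5 (1.49 ± 0.29, adjusted p = 0.0429) and the pseudokinase gene Trib3 (1.89 ± 0.33, adjusted p = 0.0244), for which n = 3 per group. These 3 lost their call without young control 1 or 3 or young ANKO 2 or 3, and Atf3 and Atf5 also without young control 2 (highest adjusted p = 0.245). The exons of Atf5 overlap Il4i1 and Nup62, and those of Gclm other genes. In the antioxidant list Gclm, a subunit of the enzyme that starts glutathione synthesis (1.37 ± 0.20, edgeR adjusted p = 0.0112), and Srxn1, which repairs peroxiredoxins (1.99 ± 0.31, adjusted p = 0.0123), rose. Both lost the call without young control 2 or 3 or young ANKO 2, and Srxn1 also without young control 1 or young ANKO 3 (highest adjusted p = 0.109). This list as a whole was not called (median 0.03, camera adjusted p = 0.275). Its count was 2 of 20 over all genes and 3 adjusted over the list alone. Adipocyte markers were lower, with Retn and Pck1 over all genes and 10 of 25 adjusted over the list alone (median -0.81, camera adjusted p = 9.53e-14; adjusted p = 0.319 with an estimated correlation). In the lipolysis list the phosphodiesterase gene Pde3b (-1.13 ± 0.21, edgeR adjusted p = 0.0400) and the nicotinic acid receptor gene Hcar2 (-1.80 ± 0.35, adjusted p = 0.0437) fell. Pde3b, Hcar2 and Pck1 kept the call only without young control 1, and Retn without young control 1 or 2 (highest adjusted p = 0.257). The lipolysis list had 9 of 18 lower adjusted over the list alone (median -0.61, camera adjusted p = 9.15e-09; adjusted p = 0.238 with an estimated correlation). Lipid synthesis genes had a median of 0.22 and were not called (camera adjusted p = 0.390).

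Mast cell protease genes were higher in young ANKO fat. Tpsb2 (1.33 ± 0.21, edgeR adjusted p = 0.0123), Mcpt4 (1.43 ± 0.24, adjusted p = 0.0207) and Cma1 (1.40 ± 0.24, adjusted p = 0.0208) rose, with n = 3 per group. All 3 lost their call without young control 2 or 3 or young ANKO 2, and Mcpt4 and Cma1 also without young ANKO 1 or 3 (highest adjusted p = 0.160). They were 3 of 16 neutrophil and mast cell markers over all genes, and 6 rose adjusted over the list alone (median 0.81, camera adjusted p = 4.28e-07; adjusted p = 0.0503 with an estimated correlation). Among genes of lipid-associated macrophages Gpnmb and the galectin gene Lgals3 (1.60 ± 0.29, edgeR adjusted p = 0.0301) rose, and kept the call only without young ANKO 1. In this list 9 of 18 genes rose adjusted over the list alone (median 1.10, camera adjusted p = 4.77e-12; adjusted p = 0.193 with an estimated correlation). Macrophage markers had a median of 0.44 and 7 of 23 higher adjusted over the list alone (camera adjusted p = 3.09e-08; adjusted p = 0.223 with an estimated correlation). Interferon-stimulated genes had a median of 0.41 and 4 of 24 higher adjusted over the list alone (camera adjusted p = 3.09e-06; adjusted p = 0.592 with an estimated correlation). Smaller shifts past the camera threshold were those of NAD metabolism (-0.11; adjusted p = 0.182 with an estimated correlation), insulin signalling (-0.24; 0.345), PPARgamma Ser273-linked genes (-0.22; 0.432), and endothelial markers (-0.21; 0.592). So were those of extracellular matrix (0.25; 0.837), thermogenic adipocyte genes (0.15; 0.592) and mammary epithelium markers (0.10; 0.837). Keratinocyte markers had a median of 2.52 (camera adjusted p = 0.0188; adjusted p = 0.592 with an estimated correlation), and 0.29 without young ANKO 2 (camera adjusted p = 0.786; 8.08e-06 to 0.786 over the alternatives). Mammary epithelium markers had a median of -0.29 without young control 3. The camera call was also lost without young control 3 for NAD metabolism (-0.05), without young control 1 for keratinocyte markers (2.55), thermogenic genes (0.08) and extracellular matrix (0.20). It was lost without young ANKO 1 or 2 for mammary markers (0.07 each), without young ANKO 2 for thermogenic genes (0.01) and without young ANKO 3 for extracellular matrix (0.20). Medians that kept the call moved to -0.13 without young control 3 for insulin signalling, to -0.06 without young ANKO 1 for NAD metabolism and to -0.14 without young ANKO 3 for endothelial markers. The thermogenic median was 0.33 without young control 3 and 0.28 without young ANKO 3, and that of extracellular matrix was 0.16 without young ANKO 1. In total camera called 15 of 40 lists, 9 higher and 6 lower. With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05), and fry called 4, which were NAD metabolism, the stress response, lipid-associated macrophages, and neutrophil and mast cells. Median, mean and test differed in sign for B and plasma cell markers (median -0.11, mean 0.06), skeletal muscle markers (median 0.27, mean 0.14, test downward) and cell death genes (median 0.02, mean -0.06).

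In old mice ANKO fat had lost most of its adipocyte transcripts relative to control fat. Cfd, the adipocyte serine protease adipsin (chromosome 10, 79890853 to 79892655), fell from 2558 ± 1727 to 74.0 ± 36.3 CPM (SD, n = 5 per group), a log2 fold change of -5.11 ± 0.51 (SE, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 6.28e-05). Rbp4 fell by 4.26 ± 0.33 on the log2 scale (edgeR adjusted p = 1.25e-05) and Retn by 4.02 ± 0.30 (adjusted p = 1.25e-05). Gys2, a glycogen synthase, had -4.70 ± 0.53 (adjusted p = 1.11e-04) and Tmem45b, a membrane protein gene whose exons overlap another gene, -4.48 ± 0.56 (adjusted p = 2.66e-04). Pon1, a lipoprotein esterase, had -4.47 ± 0.72 (adjusted p = 0.00126) and Prr32, of little known function, -4.24 ± 0.62 (adjusted p = 7.24e-04). The highest values were those of Crocc2, a ciliary rootlet gene (3.06 ± 0.49, edgeR adjusted p = 0.00128), Ache, acetylcholinesterase (2.74 ± 0.51, adjusted p = 0.00337), and Gdf15. The latter went from 1.02 ± 0.946 to 6.83 ± 2.00 CPM (SD, n = 5; log2 fold change 2.71 ± 0.55, adjusted p = 0.00577). Tpsg1, a mast cell tryptase whose exons overlap Cacna1h (2.62 ± 0.45, adjusted p = 0.00190), Lsamp, a cell adhesion gene (2.38 ± 0.51, adjusted p = 0.00764), and Cyp11a1, which starts steroid synthesis (2.33 ± 0.48, adjusted p = 0.00622), followed. The exons of Ache and Cyp11a1 overlap other genes. The naming rule required groups without overlap for these genes.

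All 25 adipocyte markers fell in old ANKO fat, by a median of -2.70 (camera adjusted p = 3.98e-32; adjusted p = 0.142 with an estimated correlation), and likewise adjusted over the list alone. Adig, an adipogenesis gene, had -3.11 ± 0.28 (edgeR adjusted p = 2.95e-05) and the lipid droplet coat gene Plin1 -3.01 ± 0.30 (adjusted p = 6.28e-05). Of 25 lipid synthesis genes 18 fell over all genes and 23 adjusted over the list alone (median -1.51, camera adjusted p = 5.17e-15; adjusted p = 0.175 with an estimated correlation). Among them were the fatty acid desaturase Scd1 (-2.83 ± 0.38, edgeR adjusted p = 3.33e-04) and the lipogenic regulator Thrsp (-2.58 ± 0.33, adjusted p = 2.66e-04). Of 18 lipolysis genes 14 fell (14 lower and 1 higher adjusted over the list alone; median -1.94, camera adjusted p = 1.25e-11; adjusted p = 0.175 with an estimated correlation). They included hormone-sensitive lipase, Lipe (-2.57 ± 0.27, edgeR adjusted p = 7.63e-05). In insulin signalling Slc2a4, the insulin-regulated glucose transporter (-1.96 ± 0.39, edgeR adjusted p = 0.00518), was among 9 lower genes of 18. Igfbp3, which binds insulin-like growth factors (1.49 ± 0.28, edgeR adjusted p = 0.00383), was the 1 higher. The list gave 1 higher and 10 lower adjusted over the list alone (median -0.45, camera adjusted p = 9.97e-04; adjusted p = 0.263 with an estimated correlation). PPARgamma Ser273-linked genes fell in 8 of 16 (1 higher and 10 lower adjusted over the list alone; median -0.70, camera adjusted p = 1.10e-05; adjusted p = 0.175 with an estimated correlation), Adipoq with -3.11 ± 0.35 among them (edgeR adjusted p = 1.08e-04). Leaving out old controls 2 and 5 moved the median of PPARgamma Ser273-linked genes to -0.36 and that of insulin signalling to -0.20, both still called by camera. With old control 5 alone left out that of the PPARgamma Ser273-linked genes was -0.41. The exons of Lipe overlap another gene.

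Mitochondrial genes were lower in old ANKO fat from both genomes. Of 47 nuclear respiratory chain genes 46 fell, and 47 adjusted over the list alone (median -0.82, camera adjusted p = 1.12e-23; adjusted p = 0.263 with an estimated correlation). Cox8a, a subunit of cytochrome oxidase, had -1.20 ± 0.18 (edgeR adjusted p = 7.53e-04). Of 13 mitochondrially encoded genes 11 fell, and 12 adjusted over the list alone (median -0.93, camera adjusted p = 1.73e-09; adjusted p = 0.263 with an estimated correlation). Among them mt-Cytb had -1.13 ± 0.18 (edgeR adjusted p = 0.00136). The nuclear list had 12 genes lower without old controls 2 and 5 (median -0.47, camera adjusted p = 9.10e-18) and the mitochondrially encoded list 5 (median -0.66, camera adjusted p = 6.91e-08). Fatty acid oxidation genes fell in 17 of 22 and in 20 adjusted over the list alone (mean -1.04, camera adjusted p = 1.25e-11; adjusted p = 0.263 with an estimated correlation), among them Hadh (-1.70 ± 0.23, edgeR adjusted p = 4.23e-04). Cholesterol synthesis genes fell in 9 of 22 and in 13 adjusted over the list alone (median -0.60, camera adjusted p = 7.35e-07; adjusted p = 0.175 with an estimated correlation), among them squalene synthase, Fdft1 (-1.07 ± 0.16, edgeR adjusted p = 7.59e-04). Thermogenic adipocyte genes fell in 6 of 20 (1 higher and 9 lower adjusted over the list alone; median -0.87, camera adjusted p = 0.0133; adjusted p = 0.512 with an estimated correlation). Antioxidant genes fell in 7 of 20 (1 higher and 9 lower adjusted over the list alone; median -0.62, camera adjusted p = 5.82e-04; adjusted p = 0.349 with an estimated correlation). They included catalase, Cat (-1.72 ± 0.27, edgeR adjusted p = 0.00109), and Sod1 (-1.18 ± 0.17, adjusted p = 5.03e-04). Hypoxia and glycolysis genes fell in 3 of 22, and in 3 adjusted over the list alone (median -0.46, camera adjusted p = 0.00123; adjusted p = 0.274 with an estimated correlation). In the stress response list 8 of 24 genes fell, such as the serine synthesis gene Phgdh (-1.62 ± 0.31, edgeR adjusted p = 0.00380), while Gdf15 rose. Adjusted over the list alone 2 were higher and 10 lower (median -0.23, camera adjusted p = 0.132). Leaving out old controls 2 and 5 moved the median to -0.55 for fatty acid oxidation, -0.23 for cholesterol synthesis, -0.19 for hypoxia and glycolysis and -0.13 for antioxidant genes, all still called by camera. The thermogenic list was then not called (-0.43, camera adjusted p = 0.0894), and its median was -0.40 with old control 2 alone left out. With old control 5 alone left out the median was -0.39 for antioxidant genes and -0.27 for hypoxia and glycolysis. The exons of Fdft1 overlap Ctsb.

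Macrophage and mast cell genes were higher in old ANKO fat. Of 23 macrophage markers 13 rose, and 17 adjusted over the list alone (median 0.69, camera adjusted p = 2.48e-10; adjusted p = 0.175 with an estimated correlation). Among them were the complement gene C1qa (0.77 ± 0.12, n = 5 per group, edgeR adjusted p = 7.50e-04) and the growth factor receptor Csf1r (0.78 ± 0.14, adjusted p = 0.00315). Of 16 neutrophil and mast cell markers 7 rose, and 10 adjusted over the list alone (median 1.34, camera adjusted p = 5.28e-08; adjusted p = 0.0327 with an estimated correlation). The mast cell proteases Mcpt4 (1.69 ± 0.18, edgeR adjusted p = 9.43e-05), Tpsb2 (1.39 ± 0.16, adjusted p = 1.08e-04) and Cma1 led this list. The chemokine Ccl8 (1.38 ± 0.24, edgeR adjusted p = 0.00202) and the anti-inflammatory cytokine Il10 (1.96 ± 0.45, adjusted p = 0.0119) were the 2 of 22 cytokine genes that rose. The count was the same adjusted over the list alone (median 0.27, camera adjusted p = 0.0250; adjusted p = 0.175 with an estimated correlation). Interferon-stimulated genes rose in 4 of 24 and in 15 adjusted over the list alone (median 0.51, camera adjusted p = 1.67e-07; adjusted p = 0.349 with an estimated correlation). The 4, Mx2, Oas2, Oasl1 and Oasl2, all lost their call without old control 2 or 5 or old ANKO 3 or 5, and Mx2 and Oas2 also without old control 1 or 3, and Mx2 and Oasl2 without old ANKO 4 (highest adjusted p = 0.116). Without old controls 2 and 5 together the interferon list kept a median of 0.44 (camera adjusted p = 1.98e-05) with none of its genes past the edgeR threshold. B and plasma cell markers had 1 gene higher, Mzb1, a chaperone of antibody secretion (1.38 ± 0.32, edgeR adjusted p = 0.0112), also adjusted over the list alone (median 1.14, camera adjusted p = 1.35e-05; adjusted p = 0.375 with an estimated correlation). Lymph node stroma markers rose in 2 of 13, also adjusted over the list alone (median 0.92, camera adjusted p = 0.00120; adjusted p = 0.370 with an estimated correlation). Of these chemokine genes Ccl19 lost its call without old ANKO 3 (adjusted p = 0.0564), and Cxcl13 kept it only without old control 3 or old ANKO 2 (highest adjusted p = 0.134). The list was not called without old controls 2 and 5 (median 0.30, camera adjusted p = 0.0985). MHC class II genes had a median of 0.68 (camera adjusted p = 2.23e-04; adjusted p = 0.393 with an estimated correlation), and T and NK cell markers one of 0.25 (camera adjusted p = 0.00120; adjusted p = 0.663 with an estimated correlation). Without old controls 2 and 5, which held few lymphocyte transcripts, the T and NK cell median was -0.34 (camera adjusted p = 1.57e-04; 5.27e-06 to 0.663 over the alternatives), while the macrophage median was 0.84 and the neutrophil and mast cell median 1.48. Without old control 2 alone the T and NK cell list was not called (median 0.0023). The cytokine list was not called without old control 1 (0.28) or old ANKO 5 (0.22), nor without old controls 2 and 5 (0.53, camera adjusted p = 0.0506). The B and plasma cell median was then 0.71 and that of MHC class II 0.43, both called by camera with none of their genes past the edgeR threshold. With old ANKO 3 alone left out the B and plasma cell median was 0.57 and that of lymph node stroma 0.42. With old control 3 alone left out it was 1.79 for B and plasma cells and 1.02 for MHC class II. The exons of Csf1r, Oasl1 and Mzb1 overlap other genes.

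Stromal genes went both ways in old ANKO fat. Fibroblast and progenitor markers rose in 6 of 21 and fell in 1 (8 higher and 1 lower adjusted over the list alone; median 0.48, camera adjusted p = 6.46e-04; adjusted p = 0.313 with an estimated correlation). The matrix gene Fbln1 had 1.46 ± 0.28 (n = 5 per group, edgeR adjusted p = 0.00466). Zfp423, which commits cells to the adipocyte lineage, fell, with -1.45 ± 0.31 (adjusted p = 0.00808). Among endothelial markers 2 rose and 4 fell (2 higher and 5 lower adjusted over the list alone; median -0.24, camera adjusted p = 0.0282; adjusted p = 0.663 with an estimated correlation). Gpihbp1, which carries lipoprotein lipase across capillaries, had -1.74 ± 0.27 (edgeR adjusted p = 9.20e-04). In the extracellular matrix list 4 of 34 rose and 3 fell (5 higher and 3 lower adjusted over the list alone; median 0.34, camera adjusted p = 0.0355; adjusted p = 0.738 with an estimated correlation). The camera call of the endothelial list was lost without old control 3 (-0.25) or 5 (-0.16) or old ANKO 3 (-0.24) or 5 (-0.15). That of the matrix list was lost without old control 1 (0.17), 3 (0.22) or 4 (0.25) or old ANKO 1 (0.26), 2 (0.21) or 5 (0.19). Leaving out old controls 2 and 5 ended the endothelial call (-0.18, camera adjusted p = 0.113) and moved the matrix median to 0.66. The progenitor median was 0.31 without old ANKO 2, and the endothelial one -0.39 without old ANKO 4. In NAD metabolism 2 of 31 rose and 6 fell (4 higher and 11 lower adjusted over the list alone; median -0.04, camera adjusted p = 0.575). There Nnmt, which methylates nicotinamide, had -2.70 ± 0.42 (edgeR adjusted p = 0.00114), and Qprt, of NAD synthesis from tryptophan, 1.02 ± 0.25 (adjusted p = 0.0159). Among senescence and p53 genes 4 of 21 fell (1 higher and 4 lower adjusted over the list alone; median 0.04, mean -0.17, test downward, camera adjusted p = 0.808). The cell cycle inhibitor Cdkn2c had -2.30 ± 0.21 (edgeR adjusted p = 2.70e-05) and the damage-response gene Gadd45a -1.06 ± 0.18 (adjusted p = 0.00170).

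The remaining lists were not called by camera in old mice. Their medians were 0.15 for lipid-associated macrophage genes, 0.23 for cell death, 0.20 for Schwann cell and nerve markers, 0.17 for immediate-early genes, 0.06 for the cell cycle and 0.09 for ribosomal proteins. They were -0.03 for glucocorticoid-responsive genes, -0.06 for the circadian clock, -0.09 for erythroid, -0.19 for mural and -0.28 for mammary epithelium markers. Median, mean and test differed in sign for skeletal muscle markers (median -0.22, mean -0.08, test upward), keratinocyte markers (median -0.07, mean 0.02, test downward) and the genes next to Adipoq (median 0.51, mean -0.06, test upward).

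In old mice 2337 of 21206 genes passed, 633 higher and 1704 lower, and 980 of them differed by at least 2-fold, 227 higher and 753 lower. The groups did not overlap in 1432 of them, which calling favours. The share of higher genes was 27.1%, and 43.6% when library totals replaced TMM factors, with 926 higher and 1199 lower. That scaling moved the median of all genes from 0.01 to 0.14. Without each of the 10 libraries in turn 1277 of the genes still passed. The count was 1539 without old control 5 (1472 of the same genes) and 1239 without old controls 2 and 5 (1006 of the same). A fit of only the old libraries gave fewer. In total camera called 23 of 40 lists, 10 higher and 13 lower, the estimated correlation left 1, neutrophil and mast cell markers, and fry called 19.

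**Figure D2:**
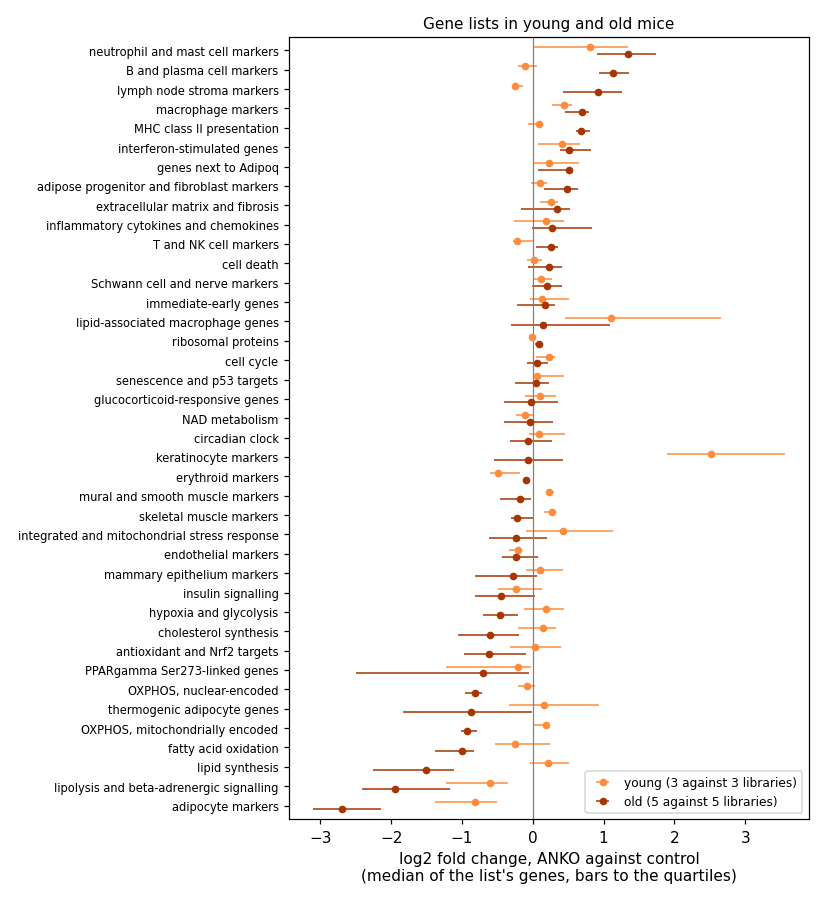
Median log2 fold change of each of the 40 gene lists, ANKO against control, in young (orange, 3 against 3 libraries) and old mice (brown, 5 against 5 libraries), with bars to the quartiles over the list's genes. Adipocyte markers lie at -0.81 in young and -2.70 in old mice, lipid synthesis at 0.22 and -1.51, and neutrophil and mast cell markers at 0.81 and 1.34.

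The genes that fell in young ANKO fat also fell in old ANKO fat, while most genes that rose in young ANKO fat were not called in old mice. Of the 32 genes lower in young mice, 30 were lower in old mice, against 2.57 for independent lists, and their median log2 fold change in old mice was -1.94. Of the 35 genes higher in young mice, 9 were higher in old mice, against 1.04 for independent lists, and their old median was 0.31. The 9 shared higher genes included Gdf15, Maoa (1.02 ± 0.25 in old mice, edgeR adjusted p = 0.0165), Tsku (0.80 ± 0.19, adjusted p = 0.0152), Mcpt4, Cma1 and Tpsb2. Zfp949, chosen after its values were seen, was another (1.25 ± 0.10 in old mice, edgeR adjusted p = 1.25e-05), at 12.9 to 20.8 CPM in all 8 controls and 36.8 to 54.4 CPM in all 8 ANKO libraries. Trib3 (-0.31 ± 0.25, edgeR adjusted p = 0.483) and Atf5 (-0.48 ± 0.22, adjusted p = 0.181) did not pass in old mice, and the difference between the ages had an edgeR adjusted p of 0.0768 for each. Across the 21206 genes the young and old effects correlated with r = 0.26 and rho = 0.187 (no libraries shared, and genes are not independent replicates), and with r = 0.605 over the 2365 genes changed at either age.

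**Figure D3:**
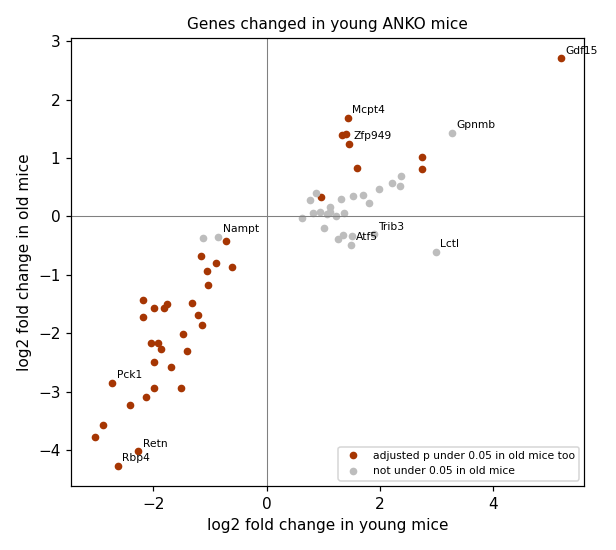
Log2 fold change of the 67 genes changed in young ANKO mice (x axis) against their log2 fold change in old mice (y axis), brown where the old difference also passed the threshold. Genes lower in young mice lie below 0 in old mice, and Trib3, Atf5 and Lctl lie above 0 in young and below 0 in old mice.

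The comparison of old with young control mice asked how the depot differs with age where Nampt is intact. Dbp, a clock output factor whose exons overlap Sphk2, fell from 90.1 ± 24.4 to 23.7 ± 3.27 CPM (SD, n = 3 and 5; log2 fold change -1.92 ± 0.24 SE, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.00461). The repressors Per2 (-1.21 ± 0.17, edgeR adjusted p = 0.00925) and Per3 (-0.97 ± 0.17, adjusted p = 0.0283) fell, and the activator Arntl rose (1.17 ± 0.18, adjusted p = 0.0145). The exons of Arntl, Fam13a, Nrg4, Krt5 and Gadd45a also overlap other genes. The hour of tissue collection is not given in the sources used here. Among the highest were Alox12e, an epidermal lipoxygenase (5.90 ± 1.04, edgeR adjusted p = 0.0299), the mucin Muc4, whose exons overlap Muc20 (5.44 ± 1.09, adjusted p = 0.0451), and the sulfotransferase Chst9 (5.02 ± 0.88, adjusted p = 0.0288). So were the transcription factor Sox14 (4.21 ± 0.75, adjusted p = 0.0294), the potassium channel Kcnd2 (4.01 ± 0.74, adjusted p = 0.0340) and the mucin-like Fcgbp (3.97 ± 0.71, adjusted p = 0.0299). Besides Dbp and Per2, the lowest were Clca1, a secreted mucus protein (-4.45 ± 0.85, adjusted p = 0.0391), and Fam13a, a gene of adipocyte lipid storage (-1.62 ± 0.33, adjusted p = 0.0451). Next were the peroxidase Gpx8 (-1.61 ± 0.28, adjusted p = 0.0283) and the adipocyte growth factor Nrg4 (-1.58 ± 0.31, adjusted p = 0.0402). Gadd45a rose by 1.16 ± 0.21 (adjusted p = 0.0340), the antibody joining chain Jchain by 2.66 ± 0.54 (adjusted p = 0.0475) and the basal epithelial keratin Krt5 by 2.30 ± 0.46 (adjusted p = 0.0451). Nampt was lower in old controls without passing the threshold (-0.52 ± 0.14, edgeR adjusted p = 0.125), and passed without old controls 2 and 5 (-0.75, adjusted p = 0.00871; 0.00871 to 0.421 over the alternatives). Dbp kept its call without each of the 8 control libraries in turn. The other genes named here lost it without young control 2 or 3 and most of them without further libraries, with a highest adjusted p from 0.0634 (Per2) to 0.256 (Jchain).

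In controls 104 genes passed with age, 89 higher and 15 lower, and 2769 had an unadjusted p under 0.05. All 104 had groups without overlap, which calling favours. The count was lower in a fit of the controls alone. It was 25, 6 and 6 without young control 1, 2 and 3, and 209, 37, 61, 23 and 212 without old control 1 to 5. Without each in turn 4 genes passed. They were Dbp and, chosen after their values were seen, the predicted genes C130026I21Rik (3.80 ± 0.30, edgeR adjusted p = 5.03e-05), AC133103.1 (4.22 ± 0.47, adjusted p = 0.00213) and Gm2619 (4.32 ± 0.53, adjusted p = 0.00430). Among the lists the clock had 2 of 19 genes higher and 4 lower (2 and 7 adjusted over the list alone; median -0.11, camera adjusted p = 0.0328; adjusted p = 0.855 with an estimated correlation). Interferon-stimulated genes had a median of -0.54 and T and NK cell markers one of -0.88 (each with camera adjusted p = 3.86e-08; adjusted p = 0.855 with an estimated correlation). Without old controls 2 and 5, which hold few lymphocyte transcripts, these medians were -0.34 and -0.25. Lipid synthesis genes had -0.62, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 5.82e-05; adjusted p = 0.855 with an estimated correlation), and nuclear respiratory chain genes -0.18 (camera adjusted p = 2.05e-05; adjusted p = 0.880 with an estimated correlation). Mammary epithelium markers had 1.41 (camera adjusted p = 9.76e-05; adjusted p = 0.855 with an estimated correlation) and cell cycle genes 0.62 (camera adjusted p = 0.0169; adjusted p = 0.908 with an estimated correlation). Neutrophil and mast cell markers had 0.69 (camera adjusted p = 0.0121; adjusted p = 0.700 with an estimated correlation). The camera call was lost without young control 3 for mammary markers (0.98), respiratory chain genes (-0.04) and the clock (-0.06). The respiratory chain call was also lost without old control 3 (-0.05), that of the clock without old control 1 (-0.10), 3 (-0.20) or 4 (-0.05), and that of the cell cycle without young control 1 (0.46) or old control 2 (0.37) or 4 (0.38). Leaving out old controls 2 and 5 moved the median to -0.53 for nuclear respiratory chain genes, -0.23 for the clock, 0.90 for mammary markers and 0.29 for neutrophil and mast cell markers. With old control 2 alone left out these were -0.33 for the respiratory chain, 0.81 for mammary markers and 0.40 for neutrophil and mast cell markers, and the clock had -0.27 without young control 2. In total camera called 18 lists, 5 higher and 13 lower, and 7 without young control 3. With an estimated correlation camera called 0 (2 at an unadjusted p under 0.05), and fry called 1, NAD metabolism. For B and plasma cell markers the median was -0.19 and the mean 0.66, and for skeletal muscle markers the median was 0.58 and the test downward.

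Camera called 10 further lists with age in controls, none of whose genes passed the edgeR threshold. The medians were negative for adipocyte markers (-0.26), lymph node stroma (-0.72), mitochondrially encoded respiratory chain genes (-0.32), lipolysis (-0.22), fatty acid oxidation (-0.20), MHC class II (-0.198), endothelial markers (-0.21) and NAD metabolism (-0.11). They were positive for macrophage markers (0.22) and lipid-associated macrophage genes (0.50). The camera adjusted p ran from 2.68e-04 for adipocyte markers to 0.0460 for macrophage markers, and the adjusted p with an estimated correlation from 0.366 for NAD metabolism to 0.908 for fatty acid oxidation. Adipocyte markers and lymph node stroma kept the camera call without each library in turn, with -0.11 and -1.11 without old control 3 and -0.49 and -0.39 without old control 5. The other 8 lost it without young control 3, NAD metabolism (-0.12) and mitochondrially encoded genes (-0.10) among them, the latter also without old control 3 (-0.22). Macrophage markers lost it without young control 1 (0.22) or 3 (0.11) or old control 2 (0.09) or 5 (0.22), and lipid-associated macrophages without young control 2 (0.47) or 3 (0.49) or old control 2 (0.05) or 5 (0.61). MHC class II lost it without young control 1 (-0.13) or 3 (-0.19) or old control 2 (-0.03) or 5 (-0.08), and endothelial markers without young control 3 (-0.15) or old control 1 to 4 (-0.20 to -0.14). Lipolysis and fatty acid oxidation lost it without young control 2 (-0.21 and -0.18) or 3 (-0.08 and -0.04) or old control 1 (-0.17 and -0.13), 3 (-0.11 and -0.04) or 4 (-0.10 and -0.07). Leaving out old controls 2 and 5 gave -0.80 for adipocyte markers, -0.58 for lipolysis and -0.62 for fatty acid oxidation, and ended the calls of lymph node stroma (-0.16), macrophages (0.06), lipid-associated macrophages (0.07) and MHC class II (0.19).

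With age, ANKO fat lost lipid synthesis and mitochondrial transcripts. Fatty acid synthase, Fasn, fell from 24013 ± 7719 to 1660 ± 515 CPM (SD, n = 3 and 5; log2 fold change -3.85 ± 0.52 SE, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 6.31e-04). Scd1 fell by 3.83 ± 0.41 on the log2 scale (edgeR adjusted p = 2.32e-04), Cfd by 4.00 ± 0.51 (adjusted p = 4.83e-04) and Aspg, an asparaginase, by 4.03 ± 0.50 (adjusted p = 4.45e-04). Cidea, a lipid droplet gene of thermogenic fat (-4.61 ± 0.70, adjusted p = 0.00160), and the fructose transporter Slc2a5 (-4.97 ± 1.21, adjusted p = 0.0254) were also among the lowest. Rising were Amtn, an enamel matrix gene (7.21 ± 1.19, edgeR adjusted p = 0.00257), Alox12e (5.08 ± 0.95, adjusted p = 0.00599) and the secreted Olfm4 (4.90 ± 0.85, adjusted p = 0.00349). Also rising were the protease inhibitor Slpi (4.70 ± 1.28, adjusted p = 0.0429), Csrnp3, a nuclear protein (4.50 ± 1.00, adjusted p = 0.0144), and Kcnd2 (4.41 ± 0.77, adjusted p = 0.00355). Exons of Olfm4, Slpi, Csrnp3, Atf5 and Dbp overlap those of other genes. Slpi lost its call without young ANKO 1, 2 or 3 or old ANKO 1, 3 or 5 (highest adjusted p = 0.212), and its value was 2.92 without old ANKO 3. Slc2a5 lost it without young ANKO 2 or 3 or old ANKO 1, 3, 4 or 5 (0.118), and Csrnp3 without young ANKO 1, 2 or 3 (0.0782). Nampt had -0.02 ± 0.15 (edgeR adjusted p = 0.963). Of 25 lipid synthesis genes 22 fell (1 higher and 22 lower adjusted over the list alone; median -2.44, camera adjusted p = 3.99e-26; adjusted p = 0.0954 with an estimated correlation). Of 25 adipocyte markers 23 fell (24 adjusted over the list alone; mean -2.06, camera adjusted p = 1.12e-27; adjusted p = 0.0978 with an estimated correlation). Nuclear respiratory chain genes fell in 40 of 47 (47 adjusted over the list alone; median -0.95, camera adjusted p = 1.44e-31; adjusted p = 0.159 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 (13 adjusted over the list alone; median -1.36, camera adjusted p = 7.36e-17; adjusted p = 0.0978 with an estimated correlation). Stress response genes fell in 9 of 24 and in 15 adjusted over the list alone (median -0.65, camera adjusted p = 8.76e-09; adjusted p = 0.0978 with an estimated correlation). The lowest p-values were those of Trib3 (-2.04 ± 0.28, edgeR adjusted p = 6.89e-04) and Atf5 (-1.62 ± 0.25, adjusted p = 0.00143). Clock genes rose in 1 of 19 and fell in 7 (2 and 10 adjusted over the list alone; median -0.46, camera adjusted p = 1.07e-04; adjusted p = 0.159 with an estimated correlation), Dbp by 1.39 ± 0.24 on the log2 scale (edgeR adjusted p = 0.00332). B and plasma cell markers rose in 6 of 24 and in 7 adjusted over the list alone (median 0.94, camera adjusted p = 1.21e-05; adjusted p = 0.389 with an estimated correlation), led by Jchain (3.16 ± 0.55, edgeR adjusted p = 0.00388). Their median was 0.46 without old ANKO 3.

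Camera called 14 further lists with age in ANKO mice. The medians were -1.13 for fatty acid oxidation, -1.02 for lipolysis, -0.84 for hypoxia and glycolysis, -0.79 for thermogenic genes, -0.652 for cholesterol synthesis, -0.54 for antioxidant genes, -0.31 for PPARgamma Ser273-linked genes and -0.15 for interferon-stimulated genes. They were 1.06 for neutrophil and mast cell markers, 0.66 for cytokines, 0.42 for the cell cycle, 0.34 for macrophages, 0.33 for progenitors and 0.11 for ribosomal proteins. The camera adjusted p was at most 0.0217, and the adjusted p with an estimated correlation ran from 0.0954 for neutrophil and mast cell markers to 0.779 for the cell cycle and ribosomal proteins. The call was lost without young ANKO 1 for cytokines (0.51) and the cell cycle (0.32), and without young ANKO 2 (0.28) or old ANKO 3 (0.23) for the cell cycle. It was lost without young ANKO 2 (0.13) or old ANKO 1 (0.26) or 2 (0.32) for progenitors, and without young ANKO 2 (0.07) or old ANKO 1 (0.10) or 3 (0.09) for ribosomal proteins. The median of PPARgamma Ser273-linked genes was -0.16 without young ANKO 1 and -0.49 without young ANKO 3, and that of interferon-stimulated genes -0.07 without old ANKO 2 and -0.25 without old ANKO 3.

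In ANKO mice 1345 genes passed with age, 380 higher and 965 lower, and 4298 had an unadjusted p under 0.05. The groups did not overlap in 1303, which calling favours. The share of higher genes was 28.3%, and 41.5% when library totals replaced TMM factors, which moved the median of all genes from 0.05 to 0.17. Gene models that overlap ribosomal RNA held 4.94 to 6.63% of the reads in young ANKO and 7.70 to 9.71% in old ANKO libraries (old controls 3.93 to 9.11%). Without abundant non-coding RNA 1343 genes passed the edgeR threshold, 1327 of them the same. Without each library in turn 319 genes passed, and the count was 336 without young ANKO 2, 678 without young ANKO 3 and 875 without old ANKO 1. In total camera called 21 lists, 7 higher and 14 lower. With an estimated correlation camera called 0 (12 at an unadjusted p under 0.05), and fry called 16. Median and mean differed in sign for extracellular matrix genes (-0.01 and 0.06), glucocorticoid-responsive genes (-0.18 and 0.03), NAD metabolism (-0.02 and 0.07) and senescence genes (0.03 and -0.04).

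The difference between the ANKO effects at both ages was tested directly. Gadd45a, a gene of the response to DNA damage and stress (chromosome 6, 67035096 to 67037457, with exons that overlap E230016M11Rik on the other strand), was the 1 gene of 21206 past the threshold (log2 difference -2.20 ± 0.29, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0400). It was higher in young ANKO libraries, at 14.8 ± 2.26 against 6.69 ± 0.984 CPM (SD, n = 3 per group), and lower in old ANKO libraries, at 7.17 ± 1.24 against 15.0 ± 3.70 CPM (n = 5 per group). Every ANKO library lay beyond every control of its age. The call was lost without young control 1, 2 or 3, young ANKO 2 or 3, old control 1 or 2, or old ANKO 1, 3, 4 or 5, with a highest adjusted p of 0.198 and values between -2.33 and -2.08. Among genes with negative differences that did not pass were the nucleotide enzyme Impdh1 (-1.20 ± 0.18), the thioesterase Acot2 (-1.24 ± 0.19), Ephx1 (-1.17 ± 0.19) and the glutathione transferase Gsta3 (-3.15 ± 0.50), each with an edgeR adjusted p of 0.0577. In the other direction C3, the central complement gene, had 1.48 ± 0.29 (edgeR adjusted p = 0.0768), Csrp2, of smooth muscle, 1.04 ± 0.24 (adjusted p = 0.156), and Tcf24, Nr5a2, Clec1b and Adam33 0.68 to 2.42 (each with adjusted p = 0.181). Nampt had 0.50 ± 0.21 (edgeR adjusted p = 0.463). The exons of Ephx1, Tcf24 and Clec1b overlap other genes. At an unadjusted p under 0.05 there were 2037 genes, DESeq2 called 274 and limma-voom 7. The edgeR count was 51 without young ANKO 1, 79 without old control 3, 10 without old ANKO 2 and 7 without old control 5.

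As lists, lipid synthesis and adipocyte genes were lower in ANKO fat, relative to control, in old than in young mice. The median difference was -2.03 for lipid synthesis (20 of 25 lower adjusted over the list alone; camera adjusted p = 4.37e-18; adjusted p = 0.198 with an estimated correlation). The lipogenic regulator Thrsp (-2.80 ± 0.52) was at an edgeR adjusted p of 0.0768. It was -1.78 for adipocyte markers (24 of 25 lower adjusted over the list alone; camera adjusted p = 4.87e-19; adjusted p = 0.239 with an estimated correlation). It was -0.77 and -1.17 for nuclear and mitochondrial respiratory chain genes (16 of 47 and 11 of 13 lower adjusted over the list alone; camera adjusted p = 1.19e-17 and 2.66e-11; adjusted p = 0.414 and 0.295 with an estimated correlation). The nuclear median was -0.42 without old controls 2 and 5, still called by camera. The exons of Atf5 overlap other genes. For the stress response it was -0.66 (11 of 24 lower adjusted over the list alone; camera adjusted p = 7.51e-10; adjusted p = 0.198 with an estimated correlation), with Atf5 (-1.97 ± 0.36) and Trib3 (-2.19 ± 0.41) each at an edgeR adjusted p of 0.0768. For cholesterol synthesis it was -0.78 (11 of 22 lower adjusted over the list alone; camera adjusted p = 3.04e-09; adjusted p = 0.198 with an estimated correlation). In total camera called 20 lists, 7 higher and 13 lower. With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05), and fry called 3, which were lipid synthesis, cholesterol synthesis and the stress response.

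**Figure D4:**
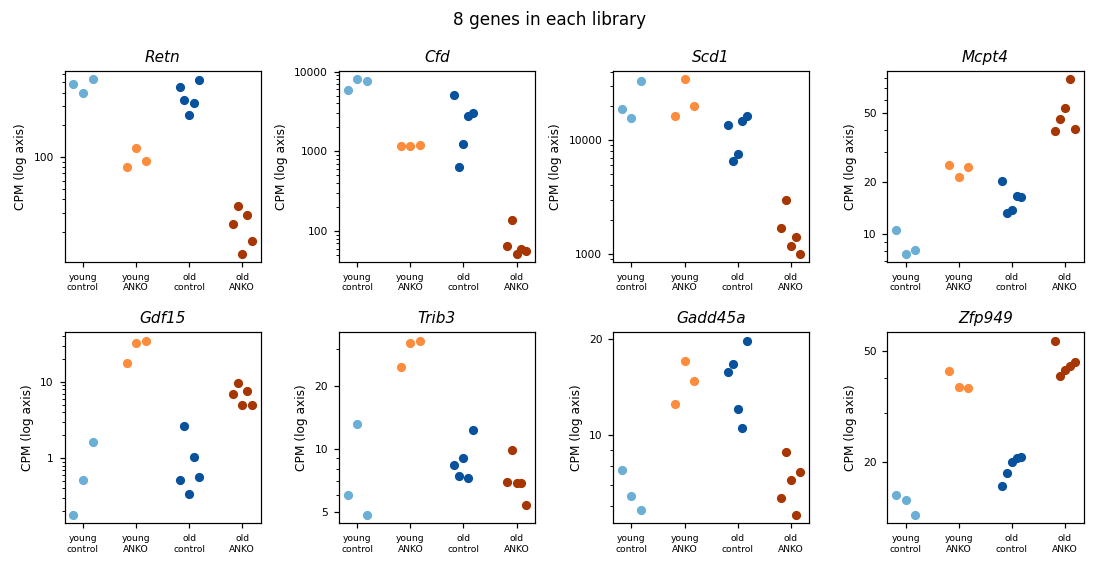
CPM on a log axis of 8 genes in each library (points), by group. Gadd45a lies at 14.8 CPM on average in young ANKO and 7.17 CPM in old ANKO libraries, against 6.69 and 15.0 CPM in the controls of the same age, and Zfp949 separates ANKO from control libraries at both ages.

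Markers of other tissues varied between libraries within groups. The median of the skeletal muscle markers ran from 1.82 CPM in old control 3 to 932 CPM in old control 5. Old controls 2 and 5 held 1.78 and 3.30 CPM of the T and NK cell markers, 2.45 and 4.67 CPM of the lymph node stroma markers and 4.84 and 8.56 CPM of the B and plasma cell markers. The other 14 libraries held at least 12.0, 30.8 and 34.2 CPM of these lists. The same 2 libraries had the highest leptin, Lep, at 1820 and 1666 CPM, against at most 339 CPM elsewhere. Csn2 was 5882 CPM in old control 2 and 805 CPM in old ANKO 5, against at most 35.2 CPM in the other libraries. Mammary epithelium markers were lowest in young control 3 (6.53 CPM), and keratinocyte markers highest in young ANKO 2 (8.61 CPM).

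**Figure D5:**
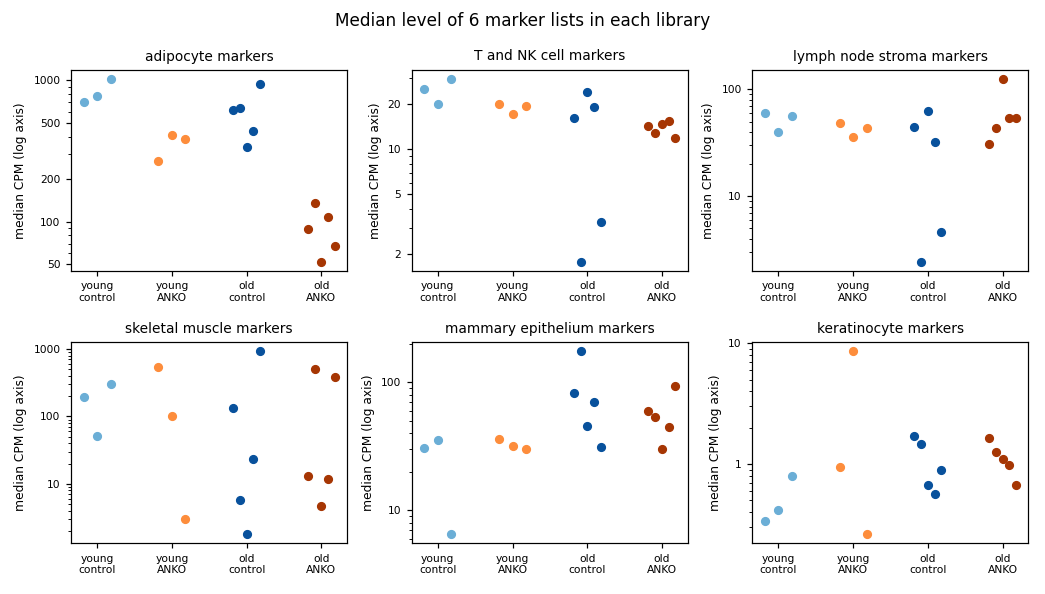
Median CPM on a log axis of 6 lists of marker genes in each library (points), by group. Adipocyte markers are at most 136 CPM in the 5 old ANKO libraries, and old controls 2 and 5 hold 1.78 and 3.30 CPM of T and NK cell markers.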

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

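The tests of explanations and of other splits given here were all chosen after the result they measure was seen, and so was the removal of old controls 2 and 5.

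The ANKO effect differed between the ages for Gadd45a and, by camera, for 20 gene lists. The difference (old minus young) was -2.20 on the log2 scale for Gadd45a. As medians it was -2.03 for lipid synthesis, -1.78 for adipocyte markers, -1.30 for lipid-associated macrophage genes and -1.17 for mitochondrially encoded respiratory chain genes. It was -0.90 for thermogenic genes, -0.84 for fatty acid oxidation and for lipolysis (-0.836), -0.78 for cholesterol synthesis and -0.77 for nuclear respiratory chain genes. It was -0.70 for hypoxia and glycolysis, -0.68 for antioxidant genes, -0.66 for the stress response and -0.37 for PPARgamma Ser273-linked genes. Positive differences were those of B and plasma cell markers (1.31), lymph node stroma (1.22), MHC class II (0.59), T and NK cells (0.45), progenitors (0.28), macrophages (0.13) and ribosomal proteins (0.0907). With an estimated correlation camera called 0 of these lists (6 at an unadjusted p under 0.05), and fry called 3. T and NK cell markers and ribosomal proteins went the other way without old controls 2 and 5 (-0.12 and -0.0093). Many of the other differences shrank without these 2 libraries: to -0.47 for lipid-associated macrophage genes, -0.43 for fatty acid oxidation, -0.42 for nuclear respiratory chain genes, -0.40 for hypoxia and glycolysis, -0.36 for thermogenic and for antioxidant genes (-0.359) and -0.33 for lipolysis. They also shrank to 0.75 for B and plasma cell markers and 0.65 for lymph node stroma, and the camera call was lost for MHC class II (0.34) and PPARgamma Ser273-linked genes (-0.11). Old control 2 left out alone gave -0.60 for lipid-associated macrophage genes, -0.53 for thermogenic genes and 0.24 for T and NK cells. Old ANKO 3 left out alone gave 0.66 for B and plasma cells, 0.70 for lymph node stroma and 0.36 for MHC class II. The replicate block gave -0.83 for lipid-associated macrophage genes. The camera call was lost without old control 5 for PPARgamma Ser273-linked genes (-0.17). For progenitors it was lost without young ANKO 2 (0.22), old control 3 (0.14) or old ANKO 1 (0.20). The macrophage call was lost without young control 2 (0.147), young ANKO 1 (0.154) or 2 (0.0524), old control 1 (0.0531), 3 (0.153) or 4 (0.0935), or old ANKO 4 (0.0699). The ribosomal protein call was lost without young control 1 (0.0665) or 2 (0.0622), young ANKO 2 (0.0434), old control 3 (0.0995) or 5 (0.0391), or old ANKO 1 (0.0702) or 3 (0.0542).

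Single libraries lay far from their group's other 4 in 26 of 196 sets of 5 values. Chance gives 1 in 20 only for independent, normal values, so no excess is shown. Old control 2 had 98.5 CPM of lipid-associated macrophage genes (median; the other old controls at most 33.6), 73.0 CPM of erythroid markers (at most 28.6) and 17.4 CPM of thermogenic genes (at most 6.88). It also had 55.2 CPM of Gys2 (at most 20.2) and 7.88 CPM of Cbr3 (at most 4.51). Old control 5 had 932 CPM of skeletal muscle markers (at most 132), 175 CPM of mural markers (at most 80.6), 425.8 CPM of Tmem45b (at most 166) and 59.2 CPM of Gsta3 (at most 31.9). Old control 4 had 5.07 CPM of cytokine genes (at most 3.46) and 10.4 CPM of Sox14 (at most 4.55). Old ANKO 2 had 137 CPM of PPARgamma Ser273-linked genes (at most 88.5), 138 CPM of Cfd (at most 64.0), 28.4 CPM of Lsamp (at most 11.9) and 9.07 CPM of Rbp4 (at most 5.99). Old ANKO 3 had 220.3 CPM of B and plasma cell markers (at most 89.0), 125 CPM of lymph node stroma markers (at most 54.4), 37.8 CPM of erythroid markers (at most 15.5) and 255 CPM of Slpi (at most 27.4). Its extracellular matrix genes were at 168 CPM (at least 276). Old ANKO 4 had 92.3 CPM of Ache (at most 25.5). Old ANKO 5 had 93.9 CPM of lipid-associated macrophage genes (at most 57.0), 105 CPM of Muc4 (at most 26.1), 11.7 CPM of Cyp11a1 (at most 5.38), 10.4 CPM of Kcnd2 (at most 4.98) and 3.15 CPM of Clca1 (at most 0.863).

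The adipocyte markers were lower in all 5 old ANKO libraries. A lower adipocyte share would raise all other cell types' markers alike. The lists below were picked after the results were seen, so this stays open. The macrophage score minus the endothelial score was 0.521 in old ANKO and -0.326 in old control libraries, a difference of 0.847 (2-sided exact permutation p = 0.00794, the smallest that 252 splits can give). The scaling of the libraries and old controls 2 and 5 alone are argued against. With library totals the median of the adipocyte markers was -2.52 with 25 of 25 genes lower, and without old controls 2 and 5 it was -1.95 with 24 of 25 lower. A change in the adipocytes themselves, or a lower adipocyte share with or without more macrophages, may underlie the pattern, and neither was settled.

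Immune markers were higher in old ANKO libraries. For T and NK cell markers the median turned from 0.25 to -0.34 without old controls 2 and 5. These held the fewest such transcripts, so their removal alone lowers it. Uneven lymph node tissue as the source stays open. For macrophage markers the median without these 2 libraries was 0.84 (13 genes higher, camera adjusted p = 9.10e-18), and for neutrophil and mast cell markers 1.48 (5 genes higher, camera adjusted p = 7.77e-09), so the 2 libraries do not account for these. With all libraries and an estimated correlation camera kept only the mast cell list, with an adjusted p of 0.0327, against 0.175 for macrophages, 0.375 for B and plasma cells, 0.393 for MHC class II and 0.663 for T and NK cells. Camera at its fixed correlation still called B and plasma cell markers (median 0.71, adjusted p = 0.00264) and MHC class II genes (0.43, 0.0327) without the 2 libraries, though none of their genes, Mzb1 included, passed the edgeR threshold, and no longer called lymph node stroma markers (0.30, 0.0985). More macrophages and mast cells in old ANKO fat, or more of these transcripts per cell, stay open.

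Other splits of the same samples into groups of the same sizes were counted. In young mice the real split gave 67 genes, the largest number in 1 of 10 splits (highest other 0), and 10 splits are too few for a share under 0.05. In old mice 1 of 100 splits gave as many as the real 2337 genes (highest other 14). In ANKO mice 1 of 56 splits gave as many as the real 1345 genes with age (highest other 0), and in both cases chance can be excluded at a share of 0.05. In control mice 2 of 56 splits gave as many as the real 104 genes with age (highest other 136). This share is under 0.05, but as another split gave more genes chance is left open. For the difference between ages 5 of 100 splits gave at least the real count of 1 gene (highest other 112), so chance is not excluded by this count. The 4 other splits with any gene all kept the real young groups, and with them the ANKO effect in young mice, so the count does not measure chance alone.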

How the results depend on the processing

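The muscle score as a covariate, the removal of old controls 2 and 5 or of old control 2, and the removal of abundant non-coding RNA were chosen after the results were seen.

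Directions held in almost all settings. Of 259 gene results, not all called, no call reversed under another scaling, filter, tool or covariate, or without any 1 library. Of these 259, RLE size factors kept 258 on their side of the threshold, the removal of abundant non-coding RNA 257, the stricter filter 255, library totals 248, DESeq2 248, the muscle score 248, no filter 232, limma-voom 225 and the replicate block 155. In a fit of only the 2 groups compared 201 of 247 kept their side, and without old controls 2 and 5, 105 of 137. Of 97 calls for gene lists RLE kept 97, the replicate block 89, the muscle score 89, fry 41 and the estimated correlation 1.

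For ANKO against control in young mice the edgeR count of 67 became 138 with library totals (66 of the same genes), 306 in a fit of the 6 young libraries alone (51 of the same), 347 with DESeq2 (67 of the same) and 37 with the replicate block (26 of the same). Without 1 library it was 10 to 48. The log2 fold change of Nampt was -0.85 with the stricter filter (edgeR adjusted p = 0.0567), -0.85 with the block (0.0733) and -0.82 with the muscle score (0.0512), each past the threshold no longer, and -0.87 to -0.80 without 1 library. Lists called went from 15 to 0 with an estimated correlation and 4 with fry, and 15 to 19 without 1 library. Mammary epithelium markers reversed to -0.29 without young control 3 (range -0.29 to 0.53 without 1 library). The test of keratinocyte markers reversed without young ANKO 2 (median 0.29, range 0.29 to 3.07 without 1 library).

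For ANKO against control in old mice the count of 2337 became 1149 in a fit of the 10 old libraries alone (1142 of the same) and 1239 without old controls 2 and 5, where fewer samples were compared. Without 1 library it was 1539 to 3380. Nampt was -0.44 to -0.24 without 1 library. Lists called went from 23 to 1 with an estimated correlation, and 20 to 24 without 1 library. T and NK cell markers reversed to -0.34 without old controls 2 and 5.

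For old against young controls the count of 104 became 60 with no filter, where more genes were tested, 4 in a fit of the 8 control libraries alone, 816 with DESeq2, 18 with limma-voom, 1 with the replicate block, 192 without old controls 2 and 5 and 37 without old control 2. Without 1 library it was 6 to 212. Nampt passed with DESeq2 (-0.52, adjusted p = 0.0382) and without old controls 2 and 5 (-0.75, edgeR adjusted p = 0.00871), and was -0.61 to -0.43 without 1 library. Lists called went from 18 to 0 with an estimated correlation, 1 with fry and 10 with the muscle score, and 7 to 19 without 1 library. Without old controls 2 and 5 the test of lipid-associated macrophage genes reversed (median 0.0716), and so did MHC class II (0.19).

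For old against young ANKO mice the count of 1345 became 2085 in a fit of the 8 ANKO libraries alone, 2290 with DESeq2 and 200 with the replicate block. Without 1 library it was 336 to 1248. Nampt was -0.05 to 0.02 without 1 library. Lists called went from 21 to 0 with an estimated correlation, and 18 to 24 without 1 library.

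For the difference between ages the count of 1 became 11 with library totals, 7 with no filter, 7 with limma-voom, 43 with the muscle score and 274 with DESeq2. With edgeR it was 0 with the stricter filter, 0 with the replicate block, 0 without old controls 2 and 5 and 0 without old control 2 (1838, 2423, 1498 and 1606 genes at an unadjusted p under 0.05). It was 0 to 79 without 1 library. Nampt was 0.41 to 0.60 without 1 library. Lists called went from 20 to 0 with an estimated correlation and 3 with fry, and 17 to 24 without 1 library. Without old controls 2 and 5 T and NK cell markers reversed to -0.12 and ribosomal proteins to -0.0093. The correlation of the young and old effects rose from 0.26 to 0.605 over the genes changed at either age, a set chosen by the effects themselves.

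Except where named above, the cause of these shifts was not tested. The depth of 19277400 to 30779300 reads limits genes of few counts. In simulated counts, where genes varied independently, 26.3% of 2-fold changes were recovered for young mice and 39.8% for old mice.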

Other observations

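The 2 tests of hypotheses given here were chosen after the result they measure was seen.

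Zfp949, chosen after its values were seen, was higher in all 8 ANKO libraries than in all 8 controls (log2 fold change 1.44 in young and 1.25 in old mice, edgeR adjusted p = 2.49e-04 and 1.25e-05). It lies on chromosome 9 at 88548020 to 88571061, far from Nampt on chromosome 12. A change in the stretch of chromosome around it, such as a segment carried along by breeding, may be the source. Of 37 tested neighbours 2 changed in 1 direction at both ages (unadjusted p under 0.05), and 0.276 of 10000 random stretches held as many. The 2 neighbours, 9430037G07Rik (-1.57 in young and -2.13 in old mice) and 9330159M07Rik (-0.91 and -0.80), both named after their values were seen, were lower in ANKO libraries, opposite to Zfp949. The neighbours therefore leave this open, since a change at Zfp949 alone needs none of them.

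The Cre transgene of the ANKO mice uses adiponectin sequences, and a transgene of that kind may carry extra copies of genes beside Adipoq. Of 7 tested genes beside Adipoq, Eif4a2 and Rfc4 were higher at both ages (unadjusted p under 0.05 each), as were 196 of 21165 genes overall. The exons of these genes overlap on opposite strands, so they were counted once, which gave a one-sided hypergeometric p of 0.0543. Counted as 2 genes the p was 0.00174. The structure of the transgene is not given in the sources used here, and the test leaves the hypothesis open.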
